A study of Arabidopsis thaliana with 8 samples.

How the data were processed

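Total RNA of imbibed seeds was sequenced on an Illumina HiSeq2500 in paired-end runs after library preparation with a TruSeq RNA kit, per the labels' protocols, which name the 2 libraries of each group as biological replicates. The p-values measure the spread between these samples. Labels gave the genotype (Col-0 or serk1-1) and the medium (without or with 200 mM NaCl, 24 h). The titles of the serk1-1 samples also contain the words wild type, and the genotype was taken from the genotype label.

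The deposited values are FPKM per gene in 1 table for the 8 libraries, made by the authors with Cufflinks 2.1.1 after FastQC 0.10.1 and alignment with TopHat2 to TAIR10, per the submitters' processing notes. The version of TopHat2, the annotation, the strand setting and the handling of reads that match several loci are not given in the sources used here. FPKM are relative to the mapped fragments of a library, so an abundant class of transcripts lowers the values of the rest. Without strand, reads of overlapping and antisense genes cannot be told apart, and values of near-identical family members such as the CRA and SESA storage genes or the LHCB and RBCS genes are uncertain. Of 33279 genes, 32815 were matched by locus to a reference table of the TAIR10.1 assembly, which was used only for names, and no coordinates are given. The depth is unknown. Whether low values lie on steps of whole fragments was checked between libraries (FPKM from 0.3 to 2, ratios within 0.015 on the log2 scale), and no step was found that gave relative depths. Exact zeros were treated as values listed at 0, because a failed estimate cannot be excluded: AT2G01021, a ribosomal DNA locus, is at 0 in replicate 2 of serk1-1 with NaCl and at 2826 to 41978 FPKM in the other 7 libraries. Folds are not given against a group at 0.

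Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for figures. Genes with at least 1 FPKM in at least 2 libraries were kept (15336 genes), and log2(FPKM + 1) was fitted with limma as 4 group means in 1 fit (4 residual degrees of freedom), with empirical Bayes moderation, a mean-variance trend and prior degrees of freedom of 3.48. The 5 comparisons were the salt effect in each genotype, the genotype effect in each medium (serk1-1 minus Col-0) and the difference of the salt effects (serk1-1 minus Col-0). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. With 2 libraries against 2, no test by exchanging library labels can fall under that threshold. Gene lists with at least 5 genes tested (18 of 23 lists) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. No list fixed beforehand kept its call with the estimated correlation. Where the median, the mean and the camera direction of a list differed in sign (23 of 90 list results), the list was not called.

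Named genes followed a rule set, like the lists and tests, before the data were examined. The rule took up to 10 genes with the largest change in each direction among called genes with a mean of at least 5 FPKM in a compared group and non-overlapping replicates, or the 5 smallest p where fewer than 5 were called. It added up to 4 genes per list and a fixed set that included SERK1, BAK1, SOS1, SOS2, SOS3, CBL10, HKT1, ABI3, ABI4, ABI5, NCED9, RAB18, EM1, EM6, GA3OX1 and GA3OX2.

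The scripts were tested on simulated data modelled on the salt effect in Col-0 (15336 genes, 200 of them changed). The changed genes were drawn only from genes whose mean on the log2 scale was at least that of 5 FPKM. Simulated libraries varied independently, without the part that real replicates share between groups. The rates therefore do not hold for weaker genes or for that shared part. At a true fold of 2, 11 of 67 changed genes were called (16.4%), at a fold of 4, 49 of 67 (73.1%), and at a fold of 8, 59 of 66 (89.4%), none in the wrong direction, with 10 unchanged genes among 129 called. A simulated shift of 1 log2 unit in the 25 storage genes was called by camera and 0 of 17 other lists were, in simulated genes that vary independently. Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, or a mean of at least 5 FPKM), median-of-ratios scaling, quantile normalization, the trend and robust options of limma, a fit of only the groups compared, a further fold limit, the replicate number as a block, and each library left out. Alternatives added after the values were seen were scaling together with the block, totals made equal, the ribosomal DNA loci left out with their share and both together, libraries left out for the lists, and the ribosomal protein list without 3 genes that its pattern took in. For further gene groups, 5 lists were written after the called genes were seen, without the genes that had prompted them. The value of 1 gene of these lists is not reported here.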

Results

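Transcript levels were measured by RNA sequencing in imbibed Arabidopsis thaliana seeds of the Columbia wild type (Col-0) and of serk1-1, a line named after SERK1, which encodes a receptor kinase of the somatic embryogenesis receptor kinase family. Seeds of each genotype were imbibed for 24 h in a liquid medium without added NaCl or with 200 mM NaCl, which gave 4 groups of 2 libraries, 8 in all. The values are FPKM, fragments normalised to transcript length and to the mapped fragments of a library, for 33279 genes. Their totals ran from 777936 to 821247 in the Col-0 libraries and from 885375 to 901215 in the serk1-1 libraries, and 18571 to 20648 genes had a value above 0. FPKM hold no read counts, so the sequencing depth of each library is unknown and no counting error could be attached to a value. Replicates correlated across genes with r = 0.968 (Col-0) and 0.977 (serk1-1) without NaCl and with r = 0.953 (Col-0) and 0.980 (serk1-1) with NaCl. The first principal component held 58.1% of the variance and placed every Col-0 library (scores from -66.0 to -18.6) apart from every serk1-1 library (22.3 to 64.6). It also placed replicate 2 above replicate 1 in all 4 groups, so it does not hold genotype alone. Replicates 1 and 2 scored -63.2 and -29.8 (Col-0) and 22.3 and 62.5 (serk1-1) without NaCl. With NaCl they scored -66.0 and -18.6 (Col-0) and 28.2 and 64.6 (serk1-1).

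Fold changes below are log2 differences of FPKM + 1 between group means, with their standard errors (n = 2 libraries per group), and understate the change of weakly expressed genes. Tests were limma's moderated tests over the 15336 genes expressed, two-sided, with Benjamini-Hochberg adjustment, and gene lists were tested with limma's camera. The median log2 fold change of all genes tested was 0.05 and -0.06 for the salt effects in Col-0 and serk1-1, -0.14 and -0.24 for the genotype effects without and with NaCl, and -0.11 for the difference of the salt effects. The camera tests compare a list with all other genes. SERK1 itself (AT1G71830) was weakly expressed. Its FPKM were 2.70 and 1.59 in Col-0 without NaCl, 2.4 and 1.06 in Col-0 with NaCl, 1.53 and 1.4 in serk1-1 without NaCl, and 1.12 and 1.05 in serk1-1 with NaCl. The genotype difference was -0.33 ± 0.33 without NaCl and -0.34 ± 0.33 with NaCl (adjusted p = 0.543 and 0.521). The labels state neither the locus nor the kind of mutation, so these values do not check the genotype. Of the other family members, BAK1 (SERK3), a co-receptor of brassinosteroid and immune receptors, had the largest genotype differences, -0.44 ± 0.20 and -0.68 ± 0.20 (adjusted p = 0.178 and 0.0776).

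The salt effect in wild-type seeds asks which transcripts differ after a day of imbibition in 200 mM NaCl. ASN1, which encodes an asparagine synthase and marks low sugar supply, rose from a mean of 4.66 to 32.0 FPKM (log2 fold change 2.53 ± 0.27, n = 2 per group, adjusted p = 0.0491). AT3G15450, an aluminium-induced protein with YGL and LRDR motifs, rose by 3.0 ± 0.27 (adjusted p = 0.0332), and GLYI7, a glyoxalase I, which detoxifies methylglyoxal, rose by 1.87 ± 0.18 (adjusted p = 0.0479). PAP17, a purple acid phosphatase, fell by 3.26 ± 0.34 (adjusted p = 0.0491). G3Pp1, a glycerol-3-phosphate transporter, fell by 2.98 ± 0.27 (adjusted p = 0.0332). Both are known as genes of phosphate starvation. The other 2 genes past the threshold were listed at 0 in both Col-0 libraries without NaCl: AT4G30097, an uncharacterised protein (8.78 and 6.68 FPKM with NaCl), and AT5G35688, a zinc metalloproteinase-like protein (4.19 and 6.32 FPKM). In total 7 genes were called, 5 higher and 2 lower, against 1740 at an unadjusted p under 0.05, where 767 would be expected by chance.

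No member of a gene list passed the test over all genes in this comparison, but several lists shifted as a whole. The list of LEA proteins, which protect cells during desiccation, was higher with NaCl. In it, 22 of 23 genes had positive values, the median was 1.18, and 15 were higher and 1 lower adjusted over the list alone (camera adjusted p = 1.05e-14; adjusted p = 0.253 with an estimated correlation). ECP31 stood at 1.96 ± 0.35 (adjusted p = 0.123), LEA76 at 1.82 ± 0.29 and EM1 at 1.46 ± 0.28. The storage protein and oil body list was also higher, with 25 of 25 genes positive, a median of 0.94 and 10 higher adjusted over the list alone (camera adjusted p = 4.30e-11; adjusted p = 0.424 with an estimated correlation). Among these, the albumin genes SESA5 and SESA4 stood at 1.62 ± 0.51 and 1.46 ± 0.23. The ABA and osmotic stress responsive list was higher (median 0.79 over 19 genes, 3 higher adjusted over the list alone, camera adjusted p = 1.29e-04; adjusted p = 0.453 with an estimated correlation), with the dehydrin LTI30 at 2.1 ± 0.56. The ABA synthesis and breakdown list was higher by a median of 0.58 over 9 genes (camera adjusted p = 0.0279; adjusted p = 0.701 with an estimated correlation). Its largest value was that of CYP707A2 (1.99 ± 0.24, adjusted p = 0.0702), a hydroxylase that breaks ABA down, and 2 of its genes were higher adjusted over the list alone.

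Cell wall loosening genes were lower with NaCl, with a median of -0.48 over 18 genes and 2 lower adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.762 with an estimated correlation). The xyloglucan endotransglucosylase XTH5 stood at -2.11 ± 0.49 and the expansin EXPA2 at -1.68 ± 0.57. The list of ribosomal proteins, drawn by a pattern of symbols, was lower by a median of -0.43 over 15 genes, with 0 called adjusted over the list alone (camera adjusted p = 5.20e-04; adjusted p = 0.701 with an estimated correlation). That pattern also took in RPP1 (AT3G44480), a disease resistance gene, and the plastid proteins RPL3P and RPL21C. The 12 genes left without these 3 gave an adjusted p of 3.24e-04. The ion transport list around the SOS pathway, which exports sodium, did not shift (15 genes, camera adjusted p = 0.885). SOS1, its sodium/proton antiporter, stood at 0.23 ± 0.26, SOS2 at 0.06 ± 0.25 and SOS3 at 0.69 ± 0.30. HKT1 was listed at 0 in all 8 libraries, CBL10 did not exceed 0.20 FPKM, and neither was tested.

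The other lists were not called in this comparison. Their camera adjusted p were 0.0915 for lipid mobilisation (18 genes), 0.166 for brassinosteroid (14), 0.223 for cell cycle and DNA replication (14) and for heat shock proteins (22), 0.252 for aquaporins (10), 0.260 for gibberellin (18), 0.410 for the ABA signalling core (24) and for photosynthesis (20), 0.570 for ethylene (14), 0.665 for oxidative stress (18) and 0.796 for the SERK family (5). Adjusted over the list alone, 3 oxidative stress genes were higher and 3 lower, 2 ethylene genes were higher, 1 brassinosteroid gene and 1 of 4 defence genes were lower, and 1 aquaporin was higher and 1 lower. The seed coat (4 genes), endosperm (1) and root hair (1) markers were too few to test as lists and held no called gene, and the list of organelle-encoded genes had no member among the genes measured. The oxidative stress genes with the largest values were GSTU5, a glutathione transferase, at 1.91 ± 0.37 and FSD1, an iron superoxide dismutase, at -1.79 ± 0.28. ABI4, a transcription factor of ABA signalling, stood at -1.02 ± 0.37 (adjusted p = 0.369). Leaving out 1 library left 0 genes for 7 of the 8 libraries and gave 38 without replicate 2 of Col-0 with NaCl. Median-of-ratios scaling gave 22, quantile normalization 14 and the replicate number as a block 1101. No label says that a replicate number marks a shared batch. Heat shock genes were higher (camera adjusted p = 1.29e-13) without replicate 1 of Col-0 with NaCl and lower (1.77e-04) without replicate 2. Of the called lists, ABA synthesis ended at 0.109, 0.0544 and 0.0574 without Col-0 replicate 2 in the medium without NaCl and replicates 1 and 2 with NaCl. Cell wall loosening ended at 0.673 and 0.479 without Col-0 replicate 1 in the medium without NaCl and replicate 2 with NaCl, and ribosomal proteins at 0.0574 without replicate 2 with NaCl.

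The salt effect in serk1-1 asks the same in the mutant. With limma, 0 genes passed the threshold, and 12 did with the replicate number as a block. The 661 genes at an unadjusted p under 0.05 were fewer than the 767 expected by chance. This does not show that NaCl had no effect, because the fit without the block leaves differences shared between replicates in its spread. The smallest p belonged to AT4G30097, listed at 0 in both libraries without NaCl and at 8.41 and 6.22 FPKM with it (adjusted p = 0.0952), and to AT3G06895, a syntaxin KNOLLE-like gene, at 0 in both libraries without NaCl and at 6.98 and 5.50 FPKM with it. CYP81D8, a cytochrome P450, stood at 1.69 ± 0.23, GASA2, a gibberellin-regulated peptide, at 1.68 ± 0.23 and ABCG31, an ABA exporter of the endosperm, at 1.7 ± 0.24 (adjusted p = 0.436 for all 3). SOS1, SOS2 and SOS3 stood at 0.16 ± 0.26, -0.23 ± 0.25 and 0.48 ± 0.30, and ABI4 at -0.75 ± 0.37.

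Of the lists in serk1-1, LEA proteins were higher with NaCl (22 of 23 genes positive, median 0.74, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.12e-16; adjusted p = 0.203 with an estimated correlation), with LEA76 at 1.36 ± 0.29 and LEA14 at 1.06 ± 0.21. Storage and oil body genes were higher (24 of 25 positive, median 0.63, 0 adjusted over the list alone, camera adjusted p = 1.34e-13; adjusted p = 0.301 with an estimated correlation), with SESA5 at 1.06 ± 0.51 and the caleosin CLO1 at 1.01 ± 0.27. The ABA and osmotic stress responsive list was higher by a median of 0.42 (1 higher adjusted over the list alone, camera adjusted p = 4.79e-06; adjusted p = 0.301 with an estimated correlation), with LTI30 at 1.54 ± 0.56 and RAP2.6 at 1.3 ± 0.29. ABA synthesis and breakdown genes were higher by a median of 0.07 (camera adjusted p = 0.0273; adjusted p = 0.872 with an estimated correlation), a call that ended at 0.288 without replicate 2 of serk1-1 without NaCl and at 0.204 without replicate 1 with NaCl. Ribosomal proteins were lower by a median of -0.43 (camera adjusted p = 6.84e-04; adjusted p = 0.872 with an estimated correlation; 5.33e-04 for the 12 genes described above). Cell wall loosening and lipid mobilisation each stood at 0.0883, gibberellin and brassinosteroid each at 0.129, and every other list at 0.276 or above. Adjusted over the list alone, 1 oxidative stress gene (FSD1, -1.68 ± 0.28) and 1 aquaporin were lower.

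The difference of the salt effects asks whether serk1-1 responds to NaCl otherwise than the wild type. With limma, 0 genes passed the threshold (smallest adjusted p = 0.99994). The 165 genes at an unadjusted p under 0.05 were fewer than the 767 expected by chance. A count below chance does not show that the responses are equal. Replicate differences correlated between the groups (0.397 to 0.720), and this fit leaves that shared part in the spread it tests against. With the replicate number as a block, 0 genes passed as well. On the log2 scale, LEA proteins shifted less with NaCl in serk1-1 than in Col-0. In this list, 22 of 23 genes had negative differences, with a median of -0.46 (camera adjusted p = 1.31e-04; adjusted p = 0.915 with an estimated correlation). EM1 stood at -0.84 ± 0.40 and ECP31 at -0.88 ± 0.49. In FPKM these 2 genes rose more in serk1-1, which started higher. EM1 went from a mean of 127 to 358 in Col-0 and from 961 to 1462 in serk1-1. ECP31 went from 136 to 508 and from 854 to 1795. The list as a whole was not compared in FPKM. The call ended at 0.0992 without replicate 1 of Col-0 without NaCl, and the median was -0.21 without replicate 1 of Col-0 with NaCl. Storage genes stood at 0.112 and every other list at 0.373 or above. Adjusted over the list alone, 1 ABA synthesis and breakdown gene was lower. CYP707A2 stood at -1.35 ± 0.34, the embryo transcription factor WOX2 at -1.51 ± 0.30, AT3G16120, a dynein light chain, at -1.78 ± 0.35, AT3G15450 at -1.63 ± 0.38 and SOS1 at -0.06 ± 0.36. AT5G35688 and AT3G06895 were the remaining 2 of the 5 smallest p, and AT5G35688 was listed at 0 in all 4 serk1-1 libraries. Across all genes, the salt effects of the genotypes, which share no library, correlated with r = 0.717 (Spearman's rho 0.706), with the same sign in 74.3% of genes. The slope of the serk1-1 effects on the Col-0 effects was 0.52, a value that noise in the Col-0 effects also lowers. The smaller shift was thus not shown to be particular to LEA proteins. Heat shock genes had a median difference of -0.46 (19 of 22 negative) and ABA responsive genes of -0.43 (15 of 19), neither called. In the reported fit the median difference was negative in every fixed list tested. Of the genes called in Col-0, 6 of 7 had the same sign in serk1-1. Genes are not independent replicates, so no p is given.

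The genotype effect without NaCl asks how serk1-1 seeds differ from wild-type seeds at the same time of imbibition. As lists, seed storage and LEA transcripts were higher in serk1-1 and cell cycle and DNA replication transcripts lower (5 of 14 genes called lower), and these list calls ended with an estimated correlation (adjusted p = 0.226, 0.226 and 0.259). CRC, which encodes the storage globulin cruciferin, rose from a mean of 385 FPKM in Col-0 to 4131 in serk1-1 (log2 fold change 3.38 ± 0.59, n = 2 per group, adjusted p = 0.0187), and EM6, a LEA protein of mature embryos, from 961 to 6133 (2.67 ± 0.44, adjusted p = 0.0157). TSO2, the small subunit of ribonucleotide reductase, which makes deoxyribonucleotides, fell from 339 to 6.79 FPKM (-5.57 ± 0.43, adjusted p = 0.00472). CYCB1;1, a mitotic cyclin, fell from 25 to 1.66 FPKM (-3.26 ± 0.37, adjusted p = 0.00573), and AT3G27630, an inhibitor of cyclin-dependent kinases, from 36.3 to 0.660 FPKM (-4.53 ± 0.32, adjusted p = 0.00472).

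Of the storage and oil body list, 17 of 25 genes rose and 0 fell over all genes, 21 rose adjusted over the list alone, and the median was 2.11 (camera adjusted p = 3.42e-16; adjusted p = 0.226 with an estimated correlation). SESA5 rose by 2.99 ± 0.51 (adjusted p = 0.0174). This list held 0.930% and 1.79% of all FPKM in Col-0 and 4.39% and 7.07% in serk1-1 without NaCl, and 1.5% and 3.15% against 6.45% and 10.1% with NaCl. In LEA proteins, 14 of 23 genes rose, 0 fell, 16 rose adjusted over the list alone, and the median was 1.17 (camera adjusted p = 8.45e-12; adjusted p = 0.226 with an estimated correlation). EM1 rose by 2.89 ± 0.28 (adjusted p = 0.00479) and ECP31 by 2.71 ± 0.35. Photosynthesis genes were higher by a median of 0.45, with 3 of 20 risen over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0195; adjusted p = 0.355 with an estimated correlation). That median was 0.56 after median-of-ratios scaling and 0.58 after quantile normalization. It was 0.29 with totals made equal and 0.27 with the ribosomal DNA loci left out as well. RBCS1A, a small subunit of Rubisco, rose by 2.18 ± 0.22 (adjusted p = 0.00479) and PSBP1, of photosystem II, by 1.44 ± 0.18. EPR1, an extensin-like gene of the endosperm and the 1 endosperm marker tested, rose from 194 to 1571 FPKM (3.0 ± 0.24, adjusted p = 0.00472).

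Of the cell cycle and DNA replication list, 5 of 14 genes fell and 0 rose over all genes, 5 fell and 1 rose adjusted over the list alone, and the median was -0.54 (camera adjusted p = 0.0163; adjusted p = 0.259 with an estimated correlation). Besides TSO2 and CYCB1;1 these were the other ribonucleotide reductase genes RNR1 (-1.63 ± 0.21) and RNR2A (-1.45 ± 0.33) and the cell cycle inhibitor KRP6 (-1.3 ± 0.19). Of the 14 genes, 10 had negative and 4 positive values. The cyclins CYCD2;1 (45.1 to 49.1 FPKM) and CYCD3;2 (20.7 to 34.3 FPKM) did not fall. The replication genes MCM4 and PCNA2 stood at -0.53 ± 0.26 and -0.56 ± 0.44 and were not called (adjusted p = 0.217 and 0.432). The 5 calls alone therefore do not show lower cell cycle activity. Cell wall loosening genes were lower by a median of -1.07, with 3 of 18 fallen over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0213; adjusted p = 0.979 with an estimated correlation). EXPA10 (-2.70 ± 0.66, adjusted p = 0.0416), EXPA2 (-2.43 ± 0.57) and XTH5 (-2.35 ± 0.49) were the 3 genes. The call of this list ended at 0.296 without replicate 1 of Col-0 and at 0.0641 without replicate 2 of serk1-1, and that of photosynthesis at 0.0627 without replicate 1 of Col-0.

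**Figure D1:**
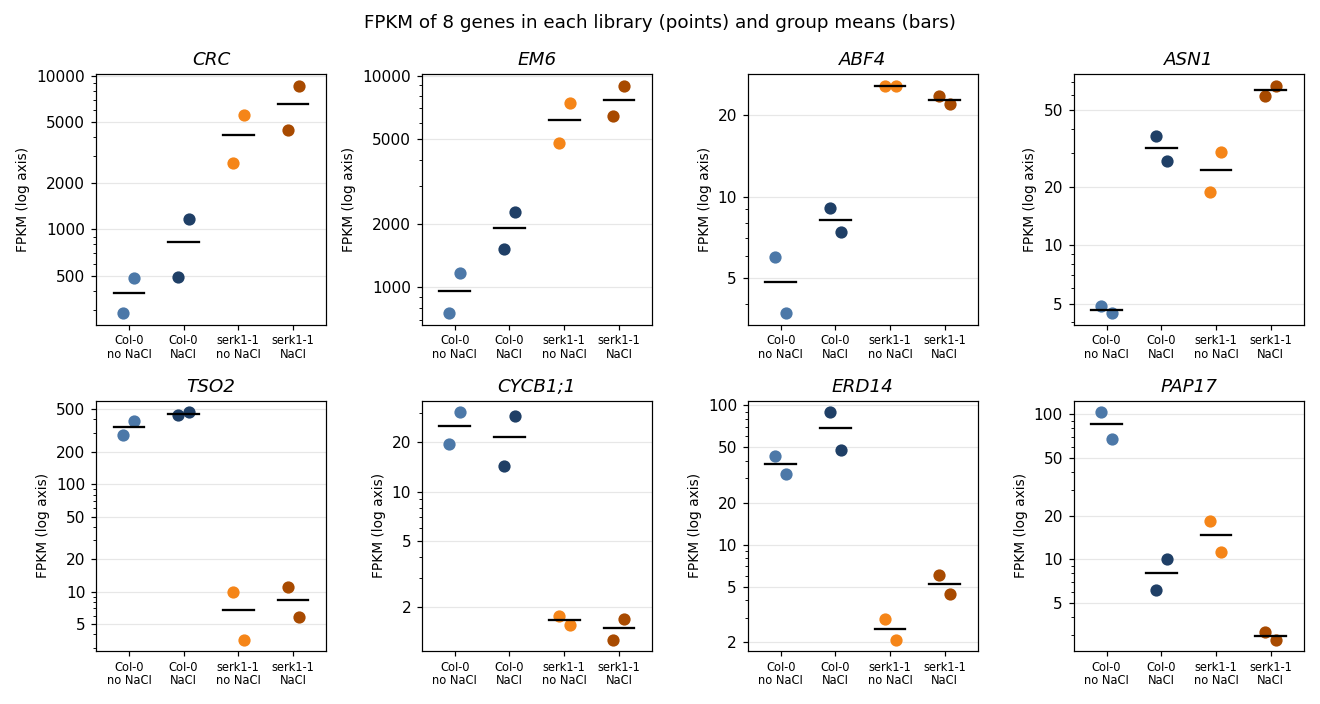
FPKM on a log axis of 8 genes in the 4 groups (Col-0 and serk1-1, without and with 200 mM NaCl); points are the 2 libraries of a group and bars the group means. CRC and EM6 lie higher in every serk1-1 library than in every Col-0 library, TSO2 and CYCB1;1 lie lower, and PAP17 lies lower with NaCl in both genotypes.

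Lists without a shift as a whole held single genes that changed. In ABA signalling, ABF4, a bZIP factor that activates ABA-responsive genes, rose by 2.22 ± 0.25 (adjusted p = 0.00573) and AFP3, an ABI5-binding protein, by 2.08 ± 0.32. ABI4 fell by 1.89 ± 0.37 (2 higher and 1 lower of 24, over all genes and adjusted over the list alone; camera adjusted p = 0.690). Among ABA and osmotic stress responsive genes, the dehydrin ERD14 fell by 3.46 ± 0.34, as did DREB2B (-1.35 ± 0.31) and ZAT10 (-1.25 ± 0.31), and RD29B rose by 1.44 ± 0.29 (1 higher and 3 lower of 19, 3 and 3 adjusted over the list alone; camera adjusted p = 0.960). NHX3, a vacuolar sodium/proton exchanger, rose by 1.72 ± 0.17 and VHA-A2, a vacuolar proton pump subunit, by 0.67 (2 higher of 15, 2 higher and 2 lower adjusted over the list alone; 0.960). SOS1 stood at -0.51 ± 0.26 (adjusted p = 0.219). In the gibberellin list the cysteine proteinase CP1 (AT4G36880) fell by 3.92 ± 0.65 and the synthesis genes KAO1 and KAO2 rose by 0.96 and 0.97 (2 higher and 1 lower of 18, 3 and 1 adjusted over the list alone; 0.798). The catalase CAT3 rose by 2.55 ± 0.42, and the ascorbate peroxidase APX1 fell by 2.2 ± 0.38 (2 higher and 3 lower of 18 oxidative stress genes, 3 and 3 adjusted over the list alone; 0.960).

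The acyl-CoA oxidase ACX2 (-1.43 ± 0.30) and the lipase SDP1 (-0.73 ± 0.19) fell, and the peroxisomal malate dehydrogenase PMDH2 rose by 1.04 ± 0.25 (1 higher and 2 lower of 18 lipid mobilisation genes, 2 and 2 adjusted over the list alone; camera adjusted p = 0.960). DWF1, which makes brassinosteroids, rose by 1.82 ± 0.41, and BRL3 and BZR1 fell by 1.53 and 1.45 (1 higher and 2 lower of 14, 2 and 3 adjusted over the list alone; 0.868). ABA1, an ABA synthesis gene, rose by 0.83 ± 0.18 (1 of 9, also adjusted over the list alone; 0.868). ACS2, an ethylene synthesis gene, rose by 1.63 ± 0.22 (1 of 14, also adjusted over the list alone; 0.960). The defence factors WRKY40 and WRKY33 fell by 1.28 and 1.26 (2 of 4, also adjusted over the list alone; not tested as a list). Heat shock (camera adjusted p = 0.960), aquaporin (0.253), ribosomal protein (0.868) and SERK family (0.960) lists held no called gene, and neither did the seed coat markers (1 of 4 higher adjusted over the list alone) nor the root hair marker. RAB18, an ABA-induced dehydrin, stood at 1.65 ± 0.50 (adjusted p = 0.0737). The seed maturation and dormancy regulators ABI3 and ABI5 stood at -0.62 ± 0.21 and 0.61 ± 0.51, the ABA synthesis gene NCED9 at -0.34 ± 0.59, and the gibberellin synthesis gene GA3OX1 at -1.06 ± 0.44 (adjusted p from 0.0958 to 0.728). GA3OX2 did not exceed 0.760 FPKM in any library and was not tested.

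In total 1697 genes differed between the genotypes without NaCl, 920 higher in serk1-1 (54.2%, 733 of them at least 2-fold) and 777 lower (620 at least 2-fold). Among the largest rises were AT2G27940, a RING/U-box protein (0.950 to 31.2 FPKM, 4.01 ± 0.29), the defensin-like LCR69 (3.87 ± 0.37), the protein repair enzyme PIMT2 (3.32 ± 0.51) and the RING ligase AIRP2, which acts in ABA signalling (3.19 ± 0.34). The largest falls after TSO2 were AT2G01422, an RNA without an annotated product (415 to 11.2 FPKM, -5.10 ± 0.19, adjusted p = 1.70e-04), AT3G27630 and the helix-loop-helix gene AT3G22100 (-4.09 ± 0.60), followed by CP1 and the thymidine kinase TK1a (-3.66 ± 0.38). Ribosomal DNA loci held 2.55% and 4.02% of all FPKM in Col-0 and 1.28% and 1.82% in serk1-1. The share of higher genes was 55.4% after median-of-ratios scaling (1112 higher, 897 lower) and 52.1% after quantile normalization (1273 and 1169). In scalings chosen after the results were seen, it was 31.8% with totals made equal (716 and 1534), 49.9% with the ribosomal DNA loci and their share taken out (917 and 921) and 28.2% with both (716 and 1825). With the replicate number as a block, 6153 genes were called, 2519 higher and 3634 lower. The count was 13, 129, 172 and 845 without replicate 2 of serk1-1, replicate 1 of Col-0, replicate 2 of Col-0 and replicate 1 of serk1-1, and 1039 and 1019 without replicates 1 and 2 of serk1-1 with NaCl.

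The genotype effect with NaCl asks how the genotypes differ in saline medium. CRC again rose (826 to 6554 FPKM, log2 fold change 3.04 ± 0.59, n = 2 per group, adjusted p = 0.0339), as did ATS3, an embryo-specific gene (5.46 to 67.4 FPKM, 3.44 ± 0.31, adjusted p = 0.0112), and EPR1 (241 to 1969 FPKM, 3.02 ± 0.24, adjusted p = 0.00805). TSO2 fell from 453 to 8.46 FPKM (-5.64 ± 0.43, adjusted p = 0.00805), AT2G01422 by 5.13 ± 0.19 from 384 FPKM (adjusted p = 1.62e-04) and AT3G27630 from 38.3 to 0.920 FPKM (-4.39 ± 0.32). SRO3 (-3.82 ± 0.82), the membrane-bound NAC factor NTL8 (-3.58 ± 0.62), the pyruvate kinase AT5G56350 (-3.57 ± 0.32) and AT2G21640, a marker of oxidative stress (-3.51 ± 0.68), fell as well. CYP707A2 was lower in serk1-1 in this medium (13.1 against 3.82 FPKM, -1.55 ± 0.24, adjusted p = 0.0229). SOS1 stood at -0.58 ± 0.26 (adjusted p = 0.189) and SOS3 at -0.41 ± 0.30.

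Of the storage and oil body list, 12 of 25 genes rose and 0 fell, 20 rose adjusted over the list alone, and the median was 1.64 (camera adjusted p = 2.06e-18; adjusted p = 0.215 with an estimated correlation). Of LEA proteins, 6 of 23 rose and 0 fell, 13 rose adjusted over the list alone, and the median was 0.83 (camera adjusted p = 5.05e-11; adjusted p = 0.215 with an estimated correlation), with EM1 at 2.05 ± 0.28 and EM6 at 2.03 ± 0.44. Of the cell cycle and DNA replication list, 4 of 14 fell, 5 adjusted over the list alone, and the median was -0.53 (camera adjusted p = 0.0206; adjusted p = 0.278 with an estimated correlation), with CYCB1;1 at -3.11 ± 0.37 and RNR1 at -1.44 ± 0.21. That call ended at 0.145 without replicate 2 of Col-0 with NaCl and at 0.0803 without replicate 1 of serk1-1 with NaCl. Photosynthesis (3 of 20 higher, RBCS1A at 1.80 ± 0.22; camera adjusted p = 0.0580) and cell wall loosening (1 of 18 lower, EXPA2 at -2.72 ± 0.57; 0.0946) were not called as lists, with the same counts adjusted over the list alone.

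**Figure D2:**
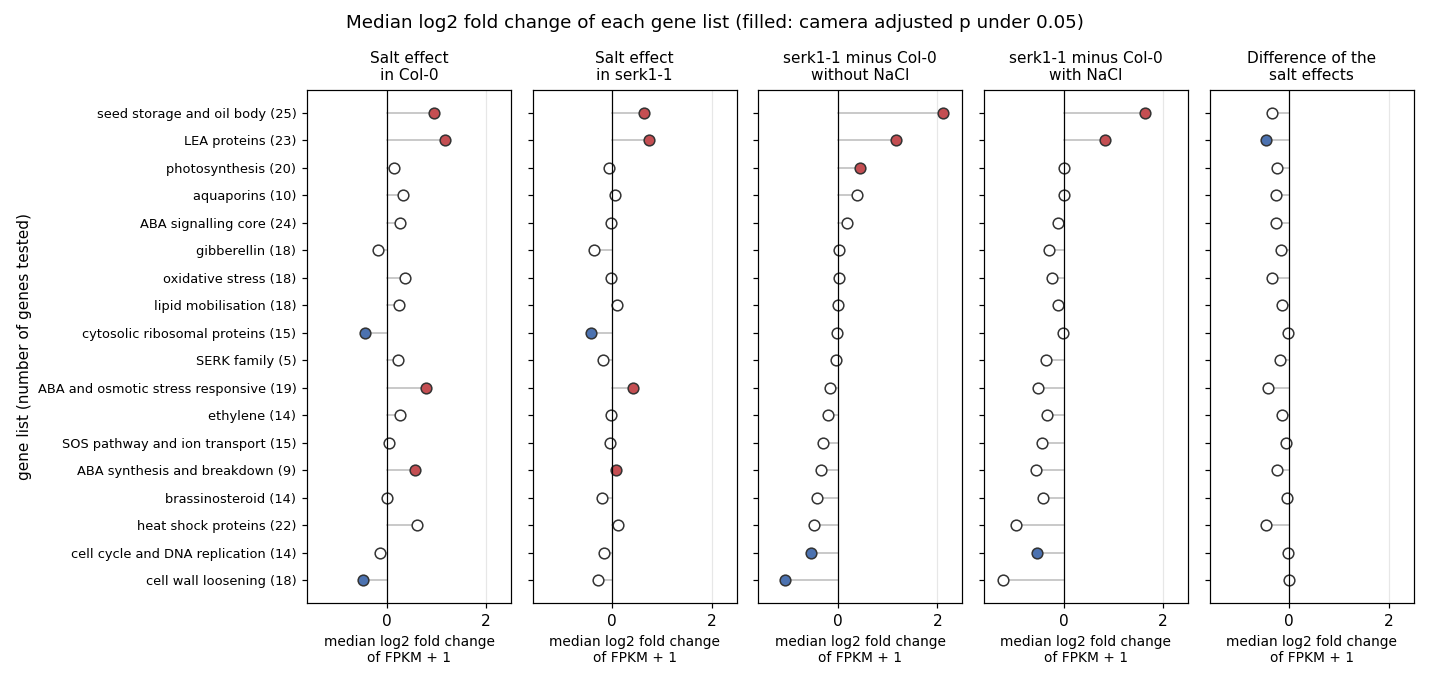
Median log2 fold change of FPKM + 1 of the 18 tested gene lists in the 5 comparisons; filled points mark lists with a camera adjusted p under 0.05 (red higher, blue lower), and the number of genes tested stands in parentheses. Storage and LEA lists lie above 0 in both salt effects and both genotype effects, and the LEA list lies at -0.46 in the difference of the salt effects.

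Other lists held few called genes with NaCl. NHX3 (1.44 ± 0.17, adjusted p = 0.0137) and VHA-A2 (0.91 ± 0.17) rose (2 of 15, 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.999). ABF4 rose by 1.37 and ABI4 fell by 1.63 ± 0.37 (1 higher and 1 lower of 24, 3 and 1 adjusted over the list alone; 0.681). ERD14 (-3.42 ± 0.34) and DREB2B (-1.80 ± 0.31) fell (2 of 19, 1 higher and 3 lower adjusted over the list alone; 0.934). APX1 (-2.11 ± 0.38), GSTU1 (-2.66 ± 0.34) and FSD1 (-1.40 ± 0.28) fell and the superoxide dismutase CSD2 rose by 1.11 (1 higher and 3 lower of 18, 2 and 4 adjusted over the list alone; 0.999). CP1 (AT4G36880) fell by 4.48 ± 0.65 (1 of 18 gibberellin genes; 0.613). ACX2 and SDP1 fell by 1.66 and 0.87 (2 of 18 lipid mobilisation genes; 0.999). ACS2 rose by 1.22 and EBF1, an F-box gene of ethylene signalling, fell by 1.39 (1 and 1 of 14; 0.999). WRKY33 fell by 1.54 (1 of 4 defence genes). ABA synthesis and breakdown had CYP707A2 alone (1 lower of 9, 1 higher and 2 lower adjusted over the list alone; 0.420). The heat shock (0.882), brassinosteroid (0.934), SERK family (0.797), aquaporin (0.648), ribosomal protein (0.420), seed coat and root hair lists held no called gene. Adjusted over the list alone, 1 SERK family gene was lower, and the counts of the gibberellin, lipid mobilisation, ethylene and defence lists were those over all genes.

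In total 962 genes differed with NaCl, 327 higher in serk1-1 (34.0%, 276 at least 2-fold) and 635 lower (551 at least 2-fold). The balance depended on scaling: 511 were higher and 539 lower after median-of-ratios scaling (48.7% higher), 765 and 751 after quantile normalization (50.5%), and, in scalings chosen after the results were seen, 279 and 972 with totals made equal (22.3%), 313 and 853 with the ribosomal DNA loci and their share taken out (26.8%), and 301 and 1502 with both (16.7%). These loci held 2.44% and 5.85% of all FPKM in Col-0 and 0.612% and 0.286% in serk1-1. The count was 9 in a fit of only the groups compared, 469 without the filter and 5869 with the replicate number as a block. It was 2, 15 and 18 without replicate 2 or 1 of serk1-1 with NaCl or replicate 1 of Col-0 with NaCl, and 672 without replicate 2 of Col-0 with NaCl. The genotype effects in the media, which share no library, correlated across genes with r = 0.896 (Spearman's rho 0.886), with the same sign in 86.5% of genes. Of the called genes, 310 were higher in both media, against 19.6 for independent lists, 485 were lower in both, against 32.2, and 0 changed in opposite directions. The 2 comparisons are not independent repeats. They share each gene's variance estimate, and replicate differences correlated between the media (0.720 in Col-0, 0.719 in serk1-1). Storage transcripts also differed between replicates within a genotype: 14 of the 25 genes were higher in replicate 2 than in replicate 1 in all 4 groups, with list medians from 0.15 to 0.76. Every serk1-1 library lay above every Col-0 library for 23 genes without NaCl and 22 with NaCl.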

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

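The tests on storage transcripts, on the replicate gradient of the DNA damage genes and on an upper limit of LEA transcripts were chosen only after the results were seen, and the lists for DNA damage, DNA replication, mitochondrial stress, phosphate and carbon starvation only after the called genes were seen. For DNA replication the bound set beforehand would exclude fewer replicating cells; it was replaced by a bound taken from all 24 DNA damage genes after the results were seen, and by that bound the test cannot tell.

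The salt effect of LEA proteins on the log2 scale differed between the genotypes by a test of the difference itself (median of serk1-1 minus Col-0 -0.46, negative in 22 of 23 genes, camera adjusted p = 0.000131). The camera adjusted p was 6.74e-10 after quantile normalization, but it decides little about scaling. Camera compares a list with the other genes, so a factor common to a library largely cancels. The median itself was -0.34 after median-of-ratios scaling and -0.49 after quantile normalization, which argues against library scaling as the whole cause. Correlated genes that move together by chance between few libraries may account for it, since p was 0.0821 with an estimated correlation (0.915 after adjustment), and a common upper limit that serk1-1 is nearer to stays open too, since its higher level with NaCl (adjusted p = 5.05e-11; adjusted p = 0.215 with an estimated correlation) would be found with or without a limit. The median ranged from -0.21 without replicate 1 of Col-0 with NaCl to -0.66 without replicate 1 of serk1-1 with NaCl, and the adjusted p from 8.24e-06 to 0.0992 (without replicate 1 of Col-0 without NaCl). A genotype difference in the response to salt stays open as the biological explanation, with no single gene past the threshold. It was not shown to be particular to LEA proteins, since the slope of the serk1-1 on the Col-0 salt effects was 0.52 over all genes.

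DNA damage response genes regulated by SOG1, the transcription factor that starts this response in plants, were lower in serk1-1: 10 of 19 genes fell without NaCl and 8 with NaCl over all genes, 13 and 12 adjusted over the list alone, all 19 had negative values in both media, and the medians were -1.81 and -1.53. The list left out the genes first seen and gave camera adjusted p of 1.01e-08 and 3.95e-07 (p = 7.90e-08 at most before adjustment; adjusted p = 0.0351 and 0.0517 with an estimated correlation), so the pattern extends beyond the first 5 genes. The gradient between replicates is argued against as the whole cause, as these 24 genes (first 5 and list) differed between replicates by a median of 0.119 (quartiles -0.36 and 0.36) against a genotype effect of -2.20. Fewer cells in DNA replication stays open, because the verdict depends on the bound. By the bound set beforehand, taken from the first 5 genes (-3.54), the 6 replication genes (median -0.78, quartiles -1.23 and -0.50) would exclude it. That bound was replaced after the results were seen, because the first 5 genes had been noticed for their large falls. Of the 6 replication genes, 3 lie under 2 FPKM in Col-0, and the other 3 had a median of -1.33. Of the 3 genes with that median, RNR1 and RNR2A had already been called lower in the fixed cell cycle and DNA replication list. A lower level of DNA damage or of SOG1 activity in serk1-1, or a difference of seed lot or age that the labels do not state, may underlie the lower DNA damage response genes and was not tested.

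Storage transcripts were higher in serk1-1 in both media, with every serk1-1 library above every Col-0 library for 23 and 22 of 25 genes (chance gives 16.7% of genes in 1 direction for 2 libraries against 2). That chance share holds for genes that do not differ. The share among all genes, many of which differed between the genotypes, was not computed. Scaling is argued against as the whole cause, since the medians were 1.78 and 1.63 after quantile normalization (camera adjusted p = 4.59e-10 at most; unscaled, adjusted p = 0.226 and 0.215 with an estimated correlation), while the replicate number as a term (1.32e-15 at most) decides nothing, because the numbers are balanced over the groups. Slower progress of the serk1-1 seeds along the gradient that also separates replicates is a candidate explanation, since the genotype effect correlated across genes with the replicate difference of the other medium's libraries (r = 0.353, and 0.415 for the reverse pair). Not all lists called for genotype without NaCl followed that gradient. The median replicate difference over all groups had the sign of the genotype effect for storage (0.35), cell wall loosening (-0.92) and cell cycle genes (-0.08). It had the opposite sign for LEA (-0.12) and photosynthesis genes (-0.14). Whether the gradient is progress of imbibition was not tested. Whether such a delay would come from the mutation or from the lot, age or storage of the seeds was not tested, since the labels give none of these. Both remain open.

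The salt effects of 4 lists written later also differed between the genotypes by the test of the difference. For DNA damage response genes the camera adjusted p was 0.000802 (median difference 0.17; adjusted p = 0.0690 with an estimated correlation), a call that ended at 0.158 without replicate 2 of Col-0 without NaCl and at 0.679 without replicate 1 of Col-0 with NaCl. For mitochondrial stress signalling it was 0.0470 (median difference -0.41; adjusted p = 0.323 with an estimated correlation), and the call ended at 0.133 with pseudocount 0.1 and without any 1 of 5 libraries (0.0830 and 0.186 without replicates 1 and 2 of Col-0 without NaCl, 0.640 without replicate 1 of Col-0 with NaCl, 0.391 without replicate 1 of serk1-1 without NaCl, 0.161 without replicate 2 of serk1-1 with NaCl). Phosphate starvation genes differed with an adjusted p of 0.000508 (median difference 0.26; adjusted p = 0.0690 with an estimated correlation), lost at 0.0862 without replicate 1 of Col-0 with NaCl. Carbon starvation genes differed with an adjusted p of 0.000182 (median difference -0.60; adjusted p = 0.0616 with an estimated correlation), lost at 0.0574 without replicate 1 of Col-0 without NaCl and at 0.224 without replicate 2 of Col-0 with NaCl.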

How the results depend on the processing

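Scaling together with the block, totals made equal, the ribosomal DNA loci left out (with or without equal totals), the libraries left out for lists, the ribosomal protein list without 3 genes and all alternatives for the 5 added lists were chosen only after the results were seen; the other alternatives were planned. Sequencing depth is unknown and limits the precision of low values by an unknown amount. Unless its construction shows it (fewer libraries, fewer residual degrees of freedom, other genes tested), the cause of a changed result was not tested.

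With pseudocount 0.1, 2 genes were called for salt in Col-0 and 2 in serk1-1; with a mean of at least 5 FPKM 0 in Col-0, and without the filter 1037 and 469 for genotype without and with NaCl. Median-of-ratios scaling gave 22 (all 7 kept) and 1, and quantile normalization 14 (6 of the 7 kept) and 1 for the salt effects and 1516 for genotype with NaCl. Without the trend there were 3 and 1 salt calls, and in a fit of only the groups compared 0 in Col-0 and 9 for genotype with NaCl. With the ribosomal DNA loci left out and totals made equal 1803 genes were called for genotype with NaCl, against 1251 with equal totals alone and 1166 with the loci and their share alone taken out. Counts of 0 are limma's, beside 1740 (salt effect in Col-0) and 661 (serk1-1) at an unadjusted p under 0.05 in the reported fit, where 767 would be expected by chance. No label says that a replicate number marks a shared batch, but the differences between replicates correlated by 0.397 to 0.720 across the 6 pairs of groups. The reported fit has no term for this shared part, so it stays in the spread that the tests use. The replicate block gave 1101, 12, 6153 and 5869 genes for salt in Col-0 and serk1-1 and genotype without and with NaCl. All genes called in the reported fit stayed called with it. With median-of-ratios scaling as well, the block gave 1035, 16, 6089 and 5383.

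Leaving out each library gave 0 to 38 salt calls in Col-0 (38 without replicate 2 of Col-0 with NaCl), 0 to 2 in serk1-1 and 0 to 2 for the difference (2 each without replicate 1 of serk1-1 with NaCl), 13 to 1889 for genotype without NaCl (13 without replicate 2 of serk1-1 without NaCl, 129 and 172 without Col-0 replicates 1 and 2, 845 without replicate 1 of serk1-1) and 2 to 672 with NaCl (2 and 15 without serk1-1 replicates 2 and 1 with NaCl, 18 without replicate 1 of Col-0 with NaCl, and 340 to 493 without any 1 library without NaCl). A group left with 1 library is assumed to vary like the others. The correlation of the salt effects was 0.660 with pseudocount 0.1 and 0.548 to 0.659 with a library left out.

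With an estimated correlation all 20 calls of the fixed lists and 15 of 17 of the added lists ended. The adjusted p were, for salt in Col-0, 0.701 (ABA synthesis, ribosomal proteins), 0.453 (ABA responsive), 0.253 (LEA), 0.424 (storage) and 0.762 (cell wall), in serk1-1 0.872 (ABA synthesis, ribosomal proteins), 0.301 (ABA responsive, storage) and 0.203 (LEA), for genotype without NaCl 0.226 (LEA, storage), 0.979 (cell wall), 0.355 (photosynthesis) and 0.259 (cell cycle), with NaCl 0.215 (LEA, storage) and 0.278 (cell cycle), and 0.915 for LEA in the difference. With the replicate block the adjusted p were 0.0669 for ABA synthesis (Col-0), 0.0642 and 0.0946 for cell cycle (genotype without and with NaCl), 0.0425 for gibberellin and 0.0484 for cell wall (salt in serk1-1) and 0.0345 for cell wall (genotype with NaCl); in the 5 added lists they were 0.0519 and 0.0718 for mitochondrial stress (salt in serk1-1 and the difference), and it changed no other list call. After quantile normalization they were 0.0555 for ABA synthesis and 0.0345 for cell wall (salt in serk1-1), 0.0298 for cell wall and 0.0414 for photosynthesis (genotype with NaCl), and 2.10e-05 for storage in the difference. With pseudocount 0.1 photosynthesis stood at 0.0460 (genotype with NaCl). Of the added lists, carbon starvation (genotype with NaCl) lost its call at 0.0562 with pseudocount 0.1 and 0.132 after quantile normalization, and mitochondrial stress (the difference) at 0.133 with pseudocount 0.1.

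With each library left out, the lowest and highest adjusted p of lists that changed sides were, for salt in Col-0, 0.0193 and 0.109 (ABA synthesis, lost without replicate 2 of Col-0 without NaCl and, at 0.0544 and 0.0574, without replicates 1 and 2 with NaCl), 2.00e-05 and 0.673 (cell wall, lost without replicate 1 of Col-0 without NaCl and, at 0.479, without replicate 2 with NaCl), 0.0120 and 0.776 (lipid mobilisation, also 0.0288 without replicate 2 of Col-0 without NaCl), 1.29e-13 and 0.362 (heat shock), 0.0188 and 0.776 (brassinosteroid), both lowest without replicate 1 of Col-0 with NaCl, and 5.25e-05 and 0.0574 (ribosomal proteins, the latter without replicate 2 of Col-0 with NaCl). In serk1-1 they were 0.00756 and 0.288 (ABA synthesis, lost without replicate 2 of serk1-1 without NaCl and, at 0.204, without replicate 1 with NaCl), 0.00556 and 0.938 (cell wall, lowest without replicate 2 of serk1-1 without NaCl), and 0.0385 and 0.404 (lipid mobilisation, lowest without replicate 1). For genotype without NaCl they were 4.67e-04 and 0.296 (cell wall) and 0.00387 and 0.0627 (photosynthesis), both highest without replicate 1 of Col-0 (cell wall also 0.0641 without replicate 2 of serk1-1), and with NaCl 0.0130 and 0.405 (cell wall, lowest without replicate 2 of Col-0 with NaCl), 0.0177 and 0.151 (photosynthesis, lowest without replicate 2 of serk1-1 with NaCl), 0.00192 and 0.145 (cell cycle, lost without replicate 2 of Col-0 with NaCl and, at 0.0803, without replicate 1 of serk1-1 with NaCl), and 2.15e-07 and 0.945 (heat shock). For the difference they were 8.24e-06 and 0.0992 (LEA, lost without replicate 1 of Col-0 without NaCl), 1.72e-08 and 0.718 (storage) and 9.12e-05 and 0.894 (cell wall), both lowest without replicate 2 of Col-0 without NaCl, 2.29e-16 and 0.786 (heat shock), and 0.0367 and 0.912 (ribosomal proteins, lowest without replicate 1 of Col-0 with NaCl). Heat shock took opposite directions: without replicate 1 of Col-0 with NaCl it was higher with salt in Col-0 (1.29e-13) and lower in serk1-1 with NaCl (2.15e-07), and without replicate 2 the reverse (1.77e-04 and 0.00193, and 3.50e-09 in the difference, where it was 0.0436 without replicate 1 of Col-0 without NaCl).

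Under these alternatives, estimated correlation apart, storage and LEA lists kept their calls in both salt and both genotype effects, as did ABA responsive genes in both salt effects and ribosomal proteins for salt in serk1-1. Of 10672 values of named genes under alternatives, none that was called changed direction, and 219 of genes called in neither setting changed sign; with a library left out, 11 to 65 called values lost their call.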

Other observations

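The gene lists in these paragraphs and the tests on them were chosen only after the called genes were seen, and they leave out the genes that had prompted them. The DNA replication list overlaps the fixed cell cycle and DNA replication list, in which its members RNR1 and RNR2A had already been called lower. PCNA2 and MCM4 are in both lists too, so the genotype test of the later list is not a separate one.

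Genes of mitochondrial stress signalling were lower in serk1-1 in both media. Of 8 genes, 4 fell without NaCl and 4 with NaCl, with medians of -1.23 and -1.65 (camera adjusted p = 0.00109 and 6.38e-05; adjusted p = 0.162 and 0.128 with an estimated correlation). AOX1A, the alternative oxidase that marks mitochondrial dysfunction, fell by 2.62 ± 0.60 and 3.21 ± 0.60, and the glucosyltransferase UGT74E2 by 2.12 ± 0.34 without NaCl. NaCl raised the list in Col-0 (median 0.80, camera adjusted p = 0.00372; adjusted p = 0.267 with an estimated correlation) and in serk1-1 (0.0325; 0.598 with an estimated correlation), where the call ended at 0.514 without replicate 2 of serk1-1 without NaCl and at 0.140 without replicate 1 with NaCl. Carbon starvation genes were higher with NaCl in Col-0 (median 1.28, 10 of 11 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.03e-06; adjusted p = 0.0276 with an estimated correlation) and in serk1-1 (median 0.53, camera adjusted p = 2.49e-04; adjusted p = 0.0655 with an estimated correlation). They were also higher in serk1-1 than in Col-0 without NaCl (6 of 11 rose and 1 fell, camera adjusted p = 0.00402; adjusted p = 0.0836 with an estimated correlation), with DRM2 at 2.96 ± 0.53 and DRM1, a gene of dormant buds, at 2.84 ± 0.47, while DIN2 fell by 1.41 ± 0.24. With NaCl the genotype effect of this list (0.0391; 0.128 with an estimated correlation) ended at 0.195 without replicate 1 of Col-0 with NaCl, at 0.0562 with pseudocount 0.1 and at 0.132 after quantile normalization, and its median went from 0.14 to -0.024 with the ribosomal DNA loci left out and totals made equal (0.028 with equal totals alone, 0.086 with the loci and their share alone taken out).

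Among DNA damage response genes, PARP2, a poly(ADP-ribose) polymerase of DNA repair, fell by 3.14 ± 0.26 in serk1-1 without NaCl and by 3.16 ± 0.26 with NaCl, and BRCA1 by 2.66 ± 0.65 without NaCl, while the end-joining genes KU70, KU80 and LIG4 did not pass the test. DNA replication genes were lower in serk1-1 (6 genes, medians -0.58 and -0.96, 2 and 1 fallen, camera adjusted p = 0.00419 and 0.0130; adjusted p = 0.134 and 0.128 with an estimated correlation), and with NaCl the call ended at 0.0957 without replicate 2 of Col-0 with NaCl. In 6 genes every serk1-1 library lay under an eighth of every Col-0 library (with at least 5 FPKM in every Col-0 library): AT2G01422, TSO2, AT3G27630, TK1a, CYCB1;1 and GR1, a gene induced by gamma radiation (9.73 against 0.645 FPKM). With the same minimum in every serk1-1 library, 0 genes went the other way, a comparison of values without a test, while limma called 920 genes higher in serk1-1 without NaCl (4677 genes in either direction at an unadjusted p under 0.05).

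That the called genes stood for wider responses was put to a test on other genes of each pathway. For carbon starvation with NaCl the larger p of the genotypes was 4.98e-05, and for mitochondrial stress in serk1-1 the larger p of the media was 4.37e-04, so those patterns extended beyond the first genes at the preset correlation. For phosphate starvation, prompted by PAP17 and G3Pp1, the list of 8 genes was lower with NaCl in Col-0 (median -0.42, camera adjusted p = 0.0222; adjusted p = 0.221 with an estimated correlation) but not in serk1-1 (p = 0.756), so the test leaves a wider response undecided. The call in Col-0 ended at 0.167 without replicate 2 of Col-0 without NaCl and at 0.165 without replicate 1 with NaCl, and the genotype effects stood at 0.109 and 0.873. SPX1, a phosphate sensor, stood at -1.96 ± 0.41 (adjusted p = 0.145).

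Heat shock genes differed between the replicates of Col-0. The list's median difference of replicate 2 minus replicate 1 was 1.61 in Col-0 without NaCl and 2.58 with NaCl, against -0.30 and 0.25 in serk1-1. Cell wall loosening genes differed by -1.21 and -1.08 in Col-0 and by -0.70 and -0.40 in serk1-1. ABI5, a transcription factor that holds back germination, had 67.9 and 33.3 FPKM in Col-0 without NaCl and 135 and 46.9 with NaCl, and its genotype effect without NaCl was 0.61 ± 0.51 (limma adjusted p = 0.463).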
